A study of Homo sapiens with 4 samples.

How the data were processed

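CLIP libraries from ultraviolet cross-linked Jurkat cells were sequenced by the authors, 2 from RNA recovered with an antibody to PCBP1 and 2 from input RNA. Per the labels' protocols, an adaptor was ligated to the 3′ end of the RNA, protein and RNA complexes were separated on a denaturing gel, and a further adaptor was ligated to the cDNA. Per the submitters' processing notes, cutadapt and STAR were used and the build was hg19. Their versions and settings, the peak caller, its filters, and whether libraries were pooled before peaks were called are not given in the sources used here. The processed data were 2 peak lists without a header, giving a chromosome, start, end and strand and a pair of numbers per peak.

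The meaning of those numbers was read from the values. The first was taken as the −log10 p of each peak as deposited by the authors. It was never negative, was 0 for every peak whose second value was 0 or less, was held by 59 peaks of list 1 and 82 of list 2 at 15.7, and ended at 400. The test behind it is not given in the sources used here. The second number was taken as the log2 fold of the immunoprecipitate over the input as deposited by the authors, with both signs and a range of −9.46 to 7.86 in list 1 and −8.28 to 7.86 in list 2. Its normalization is not given in the sources used here. The commonest log2 value was 0.19 in list 1 (15.9% of peaks) and −0.22 in list 2 (15.1%), so each list carried its own offset. Folds printed as a linear ratio were computed here as 2 raised to the authors' log2 value. Since no read counts were given per peak or per library, the depth was unknown and no precision could be given for a single fold. With no value per library, no test between libraries was made. A simulation of the effect of a shared input would also have needed values per library and was not run.

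Exact repeats of a line were counted once, which removed 409 lines of 52880 in list 1 and 429 of 55714 in list 2. A peak was called enriched at a log2 fold of at least 3 with a −log10 p of at least 3, and peaks with a log2 fold of 0 or less served as background from the same list. Overlap meant at least 1 nt on the same strand, found with bedtools 2.31.1. Its background level came from 100 placements in which every peak of the other list was shifted by 200 to 2000 nt in either direction. These shifts did not hold a peak to its exon or transcript. The level may thus lie below the overlap of unrelated peaks on the same RNAs. Peaks were matched between lists by reciprocal best overlap. Pearson and Spearman correlations used two-sided permutation tests with 100000 resamples. Chromosomes were compared by two-sided Fisher exact tests of enriched against background peaks with Benjamini-Hochberg adjustment over 25 chromosomes at 0.05, each list on its own. Odds ratios and their 95% Woolf intervals were computed with 0.5 added to each count, and stratified odds ratios used the Mantel-Haenszel method. Shares had exact Clopper-Pearson 95% intervals, and for a share of 0 the upper limit was taken as 3 counts. Sites were peaks on a strand with gaps of up to 50 nt and loci those with gaps of up to 10 kb. Peaks on a transcript are not independent of each other, so the p-values describe these lists of peaks and not a spread between cultures. The labels do not say whether the libraries came from separate cultures.

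The threshold of an enriched peak, the tests, the alternatives and the rule for named peaks were fixed before the data were examined. The rule took the 10 peaks enriched in both lists with the highest value of the smaller of their log2 folds, given by coordinates where no annotation of the build was at hand. Other sites and loci were chosen after their values were seen, and the test of neighbouring sites within 1000 nt was not among the tests fixed in advance. The alternatives among these were a −log10 p of at least 5, a log2 fold of at least 2, merging of peaks within 50 nt, overlap of at least 50% of each peak, overlap on either strand, and, for the correlation, only pairs with a −log10 p of at least 3 in either list or only pairs with a log2 fold above 0 in both. Alternatives chosen after the data were seen were a single peak per locus, all peaks that were not enriched as the background, list 2 raised to the median of list 1, repeated lines kept, and the correlation within peaks past the threshold.

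A GRCh38 annotation was compared with the lists and not used further, since coordinates of different builds cannot be mixed. In list 1, 772 peaks on 14 chromosomes lay past the last gene that this annotation places there, and 835 did in list 2. Planned tests of transcript regions, cytosine-rich sequence, splice sites, target genes and gene lists need the annotation or sequence of hg19, which were not used here, so they were not run. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data made from the 52471 peak positions of list 1. With 60.0% of peaks kept in place, 61.8% were found shared. A correlation of 0.5 was recovered as 0.500 among peaks left at identical coordinates, so the matching of peaks with differing bounds was not tested. Without an effect, 0.02 chromosomes were called per simulation over 100 simulations, and a chromosome with a 2-fold excess was called in 99% of them for chromosome 5 and in 100% for chromosome 12. Enriched labels were drawn there peak by peak, while enriched peaks of the lists lie in groups. These rates therefore do not give the error rate of the chromosome tests on the lists. Among merged sites, 3.64% had an enriched neighbour with random labels and 40.9% with planted neighbours.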

Results

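The RNA bound by PCBP1 was surveyed in Jurkat cells, a human line of malignant T cells that grows in suspension. PCBP1 (poly(C)-binding protein 1, also called hnRNP E1) is an RNA-binding protein of the KH-domain family that prefers stretches rich in cytosine. In cross-linking and immunoprecipitation (CLIP), ultraviolet light fixes proteins to the RNA they touch, an antibody recovers the protein, and the attached RNA fragments are sequenced. The study held 2 libraries of RNA recovered with an antibody to PCBP1 and 2 libraries of input RNA, to which no antibody was applied. The question put by the design was which RNAs, and which places within them, PCBP1 occupied in these cells. The measurements were 2 lists of peaks, called list 1 and list 2 below, each with a position, a strand, a log2 fold and a −log10 p for every peak. Both the log2 fold, read here as immunoprecipitate over input, and the −log10 p are the authors' own values. List 1 held 52471 distinct peaks and list 2 held 55285. The labels tie list 1 to both input libraries and list 2 to both immunoprecipitates, yet each list carried a fold and a p for every peak, so neither list was assigned to a library. No value per library was given, so read depth was unknown and no spread between libraries could be measured. The intervals below are exact binomial intervals over peaks and cover counting error only. All positions are on hg19, counted from 1. The genes at these positions are not named, because no annotation of that build was used here.

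Enriched peaks, those with a log2 fold of at least 3 and a −log10 p of at least 3, numbered 1440 in list 1 and 1162 in list 2. At a log2 fold of at least 2 there were 3051 and 2535. The 1440 and 1162 made up 2.74% of the peaks of list 1 (95% exact interval 2.61 to 2.89) and 2.10% of those of list 2 (1.98 to 2.22). Which list held more depended on the scale, since list 2 had 1625 once its log2 folds were raised to the median of list 1, an alternative chosen after the data were seen. That raise was 0.28, less than the gap between the commonest log2 folds, 0.19 in list 1 and −0.22 in list 2. Enriched peaks lay on both strands alike, with 49.9% of them on the plus strand in list 1 and 51.1% in list 2. They were wider than peaks with a log2 fold of 0 or less, with median widths of 62 and 60 nt against 28 and 27 nt. They also adjoined other peaks more often, since 49.7% of the enriched peaks of list 1 touched or overlapped another peak of that list, against 10.8% of its other peaks, and the shares in list 2 were 61.3% and 11.9%. Once peaks lying within 50 nt of each other on a strand were joined, enriched peaks occupied 1100 sites in list 1 and 817 in list 2.

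Most peaks of either list were not enriched. The median log2 fold was 0.80 in list 1 and 0.51 in list 2, a difference of 0.28 that was not removed in the values below. Peaks above 0 formed 84.5% of list 1 and 69.0% of list 2. The commonest log2 fold, 0.19 in list 1 and −0.22 in list 2, fell on opposite sides of 0. Shares, signs and odds ratios below that use a cut at 0 are therefore not on a common scale between the lists. The −log10 p was 0 for 49.1% and 58.4% of peaks. A further 537 peaks of list 1 and 423 of list 2 reached a log2 fold of 3 without a −log10 p of 3 and were not counted as enriched. Many peaks shared the same log2 fold. The 20 commonest log2 folds covered 71.2% of list 1 and 70.8% of list 2, and each corresponded to a whole multiple of a sixth of the commonest ratio, within a tolerance of 0.0001 in that multiple.

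The enriched places of list 1 were nearly all present in list 2, and the reverse. Of the 1440 enriched peaks of list 1, 1415 (98.3%, 97.4 to 98.9) were overlapped on the same strand by a peak of list 2, and 1139 of the 1162 enriched peaks of list 2 (98.0%, 97.0 to 98.7) by a peak of list 1. Peaks with a log2 fold of 0 or less were found in the other list less often, at 44.0% in list 1 (42.9 to 45.0) and 31.9% in list 2 (31.2 to 32.6). This class was not alike in the lists, since it took in the commonest log2 fold in list 2 only. Over all peaks the shares were 54.5% (54.1 to 54.9) and 52.3% (51.8 to 52.7). Being enriched in both lists was less common than being present in both. An enriched peak of list 2 overlapped 616 of the enriched peaks of list 1 (42.8%, 40.2 to 45.4), and an enriched peak of list 1 overlapped 646 of those of list 2 (55.6%, 52.7 to 58.5). As a background, the peaks of the other list were moved by 200 to 2000 nt in either direction in 100 placements, without being held to their transcripts. The mean share overlapped was then 10.2% and 9.73% for enriched peaks met by any peak, 1.60% and 1.93% for enriched peaks met by enriched peaks, and 3.89% and 2.80% for the narrower peaks of 0 or less. Observed shares were 9.62 and 10.1 times those means for enriched peaks met by any peak, and 11.3 and 11.4 times for peaks of 0 or less. Relative to the shifted level, enriched peaks were thus not found in the other list more often, though their shares were already near 100%. For enriched peaks, none of the 100 placements came above 12.6% when met by any peak or 3.36% when met by enriched peaks. The share of enriched peaks that were enriched in both lists depended on the threshold: at a log2 fold of at least 2 it was 61.4% for list 1 and 77.0% for list 2.

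**Figure D1:**
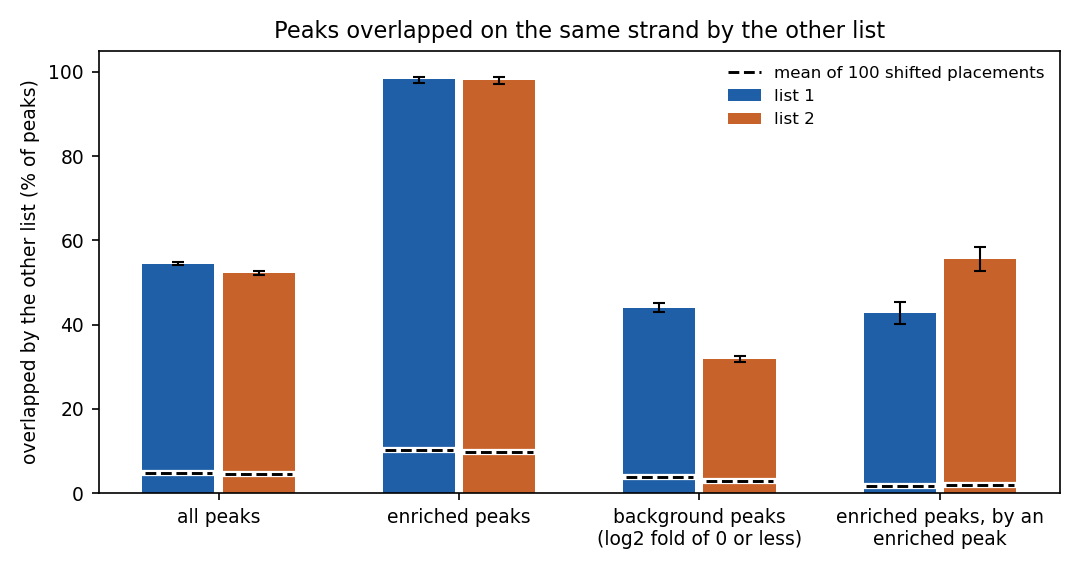
Bars give the percentage of peaks of list 1 (blue) and list 2 (orange) overlapped on the same strand by the other list, with 95% exact binomial intervals, and dashed lines give the mean of 100 shifted placements. Enriched peaks reached 98.3% and 98.0%, while 42.8% and 55.6% of them were overlapped by a peak that was itself enriched.

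Peaks found at the same place carried related folds in the 2 lists. Pairing each peak with its best overlap gave 26418 pairs, of which 164 had identical coordinates. Across these pairs the log2 folds had a Pearson r of 0.62 and a Spearman rho of 0.56, each with a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give, and the same after Benjamini-Hochberg adjustment over the 2 relations. The rho was 0.29 among pairs with a −log10 p of at least 3 in either list. Among pairs enriched in both it was 0.32, with a Pearson r of 0.58. It was −0.19 among pairs enriched in either list, a selection made after the data were seen that leaves out pairs moderate in both. The sign of the log2 fold was the same in 80.8% of pairs, against 73.8% if the signs had been independent, and the median absolute difference was 0.70. In 502 pairs both peaks were enriched, against 47.2 if enrichment in the lists had been independent, and 1597 pairs passed in both at a log2 fold of at least 2. The median log2 fold of the 502 pairs was 3.67 in list 1 and 3.66 in list 2, and 242 of them lay on the plus strand and 260 on the minus strand. A further 765 pairs were enriched in list 1 alone. Of those, 762 had a log2 fold above 0 in list 2, where their median was 2.30 against 3.56 in list 1. In the 482 pairs enriched in list 2 alone, all were above 0 in list 1, with a median of 2.39 there and 3.55 in list 2. These correlations are across peaks, which are not independent replicates. Whether the lists share an input library is not given in the sources used here, and a shared input would raise both the correlation and the number of pairs enriched in both.

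**Figure D2:**
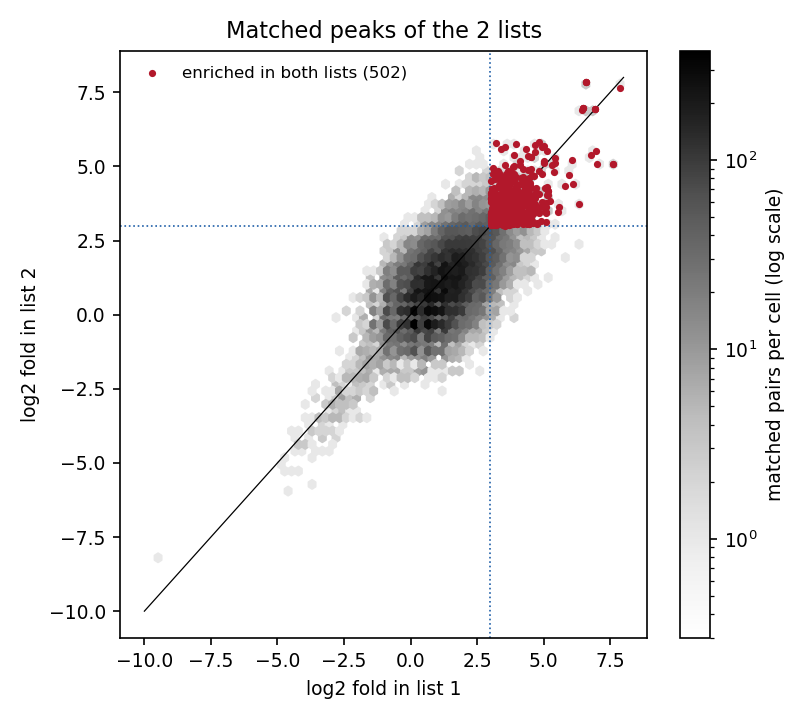
Each cell counts matched pairs of peaks by their log2 fold in list 1 (horizontal) and list 2 (vertical), on a log grey scale, with the 502 pairs enriched in both lists in red, dotted lines at a log2 fold of 3 and a solid line of equality. The pairs follow the line of equality loosely, with a Pearson r of 0.62, and a lone pair lies at −9.46 and −8.28.

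The strongest repeated enrichment was on the plus strand of chromosome 8, at 11696283 to 11696348, with a log2 fold of 7.86 in list 1 and 7.64 in list 2 (232-fold and 199.8-fold). Next came the plus strand of chromosome 6 at 31958260 to 31958279, with 6.92 in each list. On the minus strand of chromosome 15, at 96826150 to 96826168, the log2 fold was 6.60 in list 1 and 7.86 in list 2. On the minus strand of chromosome 13, at 24308536 to 24308558, the highest values were 6.48 and 6.95. These 4 sites held the 10 matched peaks with the highest log2 fold in the weaker of the 2 lists, because on chromosomes 6, 15 and 13 the authors' lists divide a short stretch into several peaks of 2 to 13 nt with equal or nearly equal folds. The −log10 p of all 10 peaks was 15.7, a value shared by 59 peaks of list 1 and 82 of list 2, except that list 1 gave 400 on chromosome 15. The value 400 was the highest of either list, held by 17 peaks of list 1 and 9 of list 2. Values shared in this way do not rank peaks by strength of evidence. Counted by sites, the 502 pairs fell into 406 sites with a median length of 80 nt (quartiles 59 and 106).

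Below these 4, and chosen after their values were seen, stood sites on several other chromosomes. The minus strand of chromosome 2 at 230045642 to 230045695 reached 6.97 in list 1 and 5.51 in list 2. Chromosome 11 held a site on its minus strand at 32165334 to 32165357, with 7.61 and 5.07, and another at 61732159 to 61732207, with 6.99 and 5.07. Chromosome 19 held several of the leading sites, all but the last of these on its minus strand. At 47990941 to 47991124 the highest log2 folds were 5.97 and 5.30, at 45981855 to 45981875 they were 5.12 and 5.52, at 13064978 to 13065076 they were 5.42 and 5.10, at 1598149 to 1598215 they were 4.95 and 5.66, and on the plus strand at 36149543 to 36149642 they were 5.37 and 5.47. That plus-strand site held 2 pairs, and its highest values in the 2 lists came from different pairs. Its lowest values were 4.68 in list 1 and 4.82 in list 2. On the plus strand of chromosome 7, at 139025478 to 139025521, the log2 folds were 4.84 and 5.82. The −log10 p there was 400 in both lists, the highest value of either list.

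Enriched peaks also came in groups along a strand. With gaps of up to 10 kb allowed, the 502 pairs fell into 352 loci, of which 257 held a single pair, 95 held 2 or more, and 7 held 5 or more. Those 7 loci held 41 of the pairs (8.17%). Part of this grouping lay within single sites, since the 502 pairs made 406 sites, of which 66 held several pairs. The minus strand of chromosome 11 had the fullest locus, with 9 pairs between 65622337 and 65622809. All 14 peaks of list 1 in that stretch were enriched, with log2 folds from 3.03 to 5.83 and a median of 3.97. In list 2, 12 of 15 peaks were enriched, with log2 folds from 2.73 to 5.58 and a median of 4.03. The minus strand of chromosome 5 at 140953177 to 140953527 held 6 pairs, with highest log2 folds of 4.84 and 4.51, and the minus strand of chromosome 11 at 3848227 to 3848799 held 6, with 4.23 and 4.63. The other 4 loci, each of 5 pairs, lay on chromosome X (plus strand, 64959888 to 64960976), chromosome 7 (minus strand, 5568256 to 5568301), chromosome 12 (minus strand, 15095152 to 15095458) and chromosome 5 (plus strand, 133474644 to 133483221). On chromosome 7 all 5 pairs lay within 46 nt, and so within a single site, with log2 folds from 3.37 to 4.37 in list 1 and from 3.34 to 4.18 in list 2. These loci were chosen after their values were seen.

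**Figure D3:**
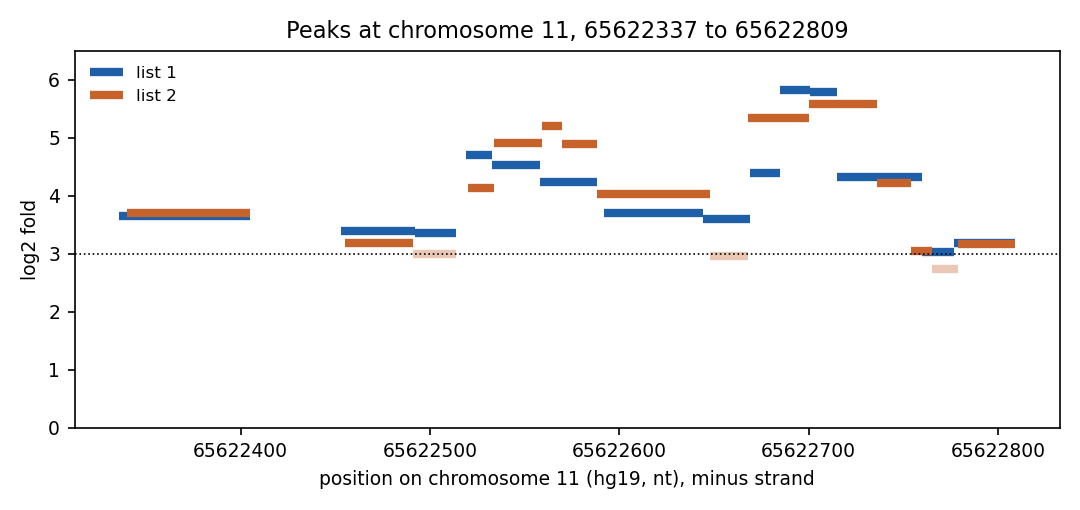
Horizontal bars are the peaks of list 1 (blue) and list 2 (orange) on the minus strand of chromosome 11 (hg19 position in nt), placed at their log2 fold, with paler bars for peaks that were not enriched and a dotted line at 3. Both lists are highest between 65622669 and 65622736, reaching 5.83 in list 1 and 5.58 in list 2.

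Chromosome 19 held more of the enriched peaks than its share of peaks at or below the input in both lists, and so did chromosomes 11 and X, while chromosomes 1, 2, 4, 14, 15 and 18 held fewer. For chromosomes X, 1, 14 and 15 this did not hold under every setting, as given below. On chromosome 19, 4.30% of the peaks of list 1 were enriched (95% exact interval 3.68 to 4.996) and 3.59% of those of list 2 (3.05 to 4.19). The odds of lying on chromosome 19 were 2.34 times higher for enriched peaks than for peaks with a log2 fold of 0 or less in list 1 (1.93 to 2.82, Fisher exact test, adjusted p = 3.404e-15) and 2.74 times higher in list 2 (2.29 to 3.29, exact adjusted p = 1.883e-21). With all peaks that were not enriched as the background, chosen after the data were seen, the odds ratios fell to 1.68 and 1.85. The peaks of chromosome 19 had median log2 folds of 1.19 and 0.89, against 0.80 and 0.51 over each whole list. For chromosome 11 the odds ratios were 1.54 and 1.83. At the other end, 0.727% of the peaks of chromosome 4 were enriched in list 1 and 0.650% in list 2, with odds ratios of 0.227 and 0.247. Chromosome 18 had odds ratios of 0.342 and 0.0834, with 0.5 added to each count as for every odds ratio by chromosome. The latter rested on 1 enriched peak against 261 of 0 or less, and was 0.0557 without that addition. Over all settings the odds ratio of chromosome 18 ran from 0.225 to 0.408 in list 1 and from 0.0409 to 0.320 in list 2, the highest in list 2 at a log2 fold of at least 2, and that of chromosome 4 from 0.135 to 0.371 and from 0.247 to 0.397. Chromosome 2 had 0.482 and 0.425.

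Over the 25 chromosomes tested, counting X, Y and the mitochondrial chromosome, 12 passed an adjusted p of 0.05 in list 1 (5 higher and 7 lower) and 14 in list 2 (5 higher and 9 lower), by two-sided Fisher exact tests with Benjamini-Hochberg adjustment. The 9 chromosomes named above passed in the same direction in both. When a single peak was kept per locus, an alternative chosen after the data were seen, the calls of chromosomes X, 1, 14 and 15 ended in both lists, with exact adjusted p values from 0.129 to 1. Fewer peaks entered these tests, and the odds ratios in list 1 and list 2 were then 0.656 and 0.607 for chromosome 14 (from 0.568 and 0.466), 0.670 and 0.584 for chromosome 15 (from 0.558 and 0.473) and 1.496 and 1.04 for chromosome X (from 1.88 and 1.48). For chromosome 1 they were 1.11 and 0.800 (from 0.733 and 0.692), so its direction turned in list 1. With all peaks that were not enriched as the background, also chosen after the data were seen, the calls of chromosome X in list 2 and chromosome 14 in list 1 ended (exact adjusted p = 0.116 and 0.0843), at odds ratios of 1.37 and 0.701. Those of chromosomes 11, 19, 2, 4 and 18 passed under every setting tried. Across the 23 chromosomes other than Y and the mitochondrial chromosome, the enriched share in list 1 and that in list 2 had a Pearson r of 0.87 and a Spearman rho of 0.91 (permutation p = 1e-05 for each), and r was 0.84 without chromosomes X and 19. On chromosome Y, 0 of 30 peaks of list 1 and 0 of 45 peaks of list 2 were enriched, which allows shares of up to 10% and 6.67%.

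**Figure D4:**
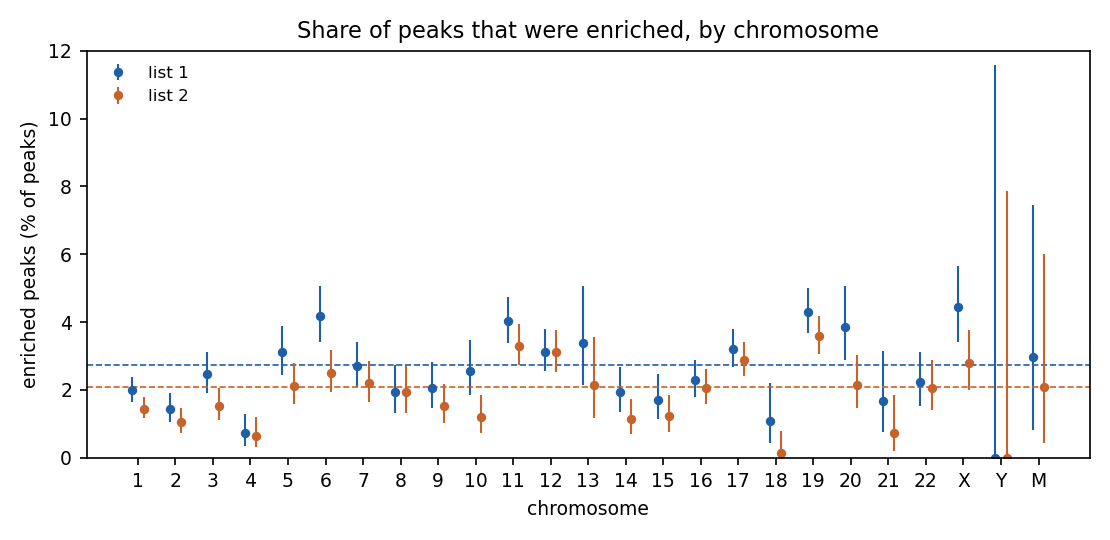
Points give the percentage of peaks that were enriched on each chromosome in list 1 (blue) and list 2 (orange), with 95% exact binomial intervals, and dashed lines give the share over all peaks of each list (2.74% and 2.10%). Chromosome 19 lies above the dashed line in both lists, and chromosomes 4 and 18 lie below it.

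Mitochondrial RNA was mostly at or below the input level, apart from a few places. Of the peaks on the plus strand of the mitochondrial chromosome, 76 of 127 in list 1 and 90 of 138 in list 2 had a log2 fold of 0 or less, and the medians were −0.16 and −0.37. The minus strand went the other way, with 7 peaks in list 1 and 5 in list 2 and medians of 0.72 and 0.63. Of these peaks, 2 in list 1 and 1 in list 2 had a log2 fold of 0 or less. The same 2 minus-strand peaks were enriched in each list. At 5828 to 5858 the log2 folds were 4.55 and 4.71 (23.5-fold and 26.1-fold) with a −log10 p of 400, the highest of either list, in both. At 15957 to 15989 they were 6.08 and 5.20. On the plus strand, the enriched peaks lay at 4302 to 4330 in list 1 (3.15) and 4304 to 4329 in list 2 (4.85), and at 10009 to 10047 in list 1 alone (4.24). Over both strands, 2.99% of the mitochondrial peaks of list 1 were enriched, against 2.74% of all its peaks, while 78 of 134 had a log2 fold of 0 or less. Set against those low peaks, the odds ratio of enriched peaks was 0.321 in list 1 (exact adjusted p = 0.0171). In list 2 the odds ratio was 0.562 (exact adjusted p = 0.377), and the difference between the lists was not tested.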

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

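The values that moved under an alternative follow. With a log2 fold of at least 2, enriched peaks numbered 3051 in list 1 and 2535 in list 2, and pairs enriched in both lists 1597. When at least 50% of each peak had to be covered, 39.6% of list 1 and 37.7% of list 2 were shared. The share of enriched peaks overlapped by an enriched peak was 50.1% in list 1 and 64.8% in list 2 with a −log10 p of at least 5, 61.4% and 77.0% with a log2 fold of at least 2, and 35.2% and 43.7% with coverage of at least 50%. With list 2 raised to the median of list 1, chosen after the data were seen, it was 52.0% and 49.2%, so which list had the larger share turned. That raise was smaller than the gap between the commonest log2 folds of the lists, so it did not line those values up. The Spearman rho of the log2 folds was 0.59 with coverage of at least 50%, 0.47 among pairs above 0 in both lists and 0.29 among pairs with a −log10 p of at least 3 in either list (permutation p = 1e-05 for each). Among the 1749 pairs past the threshold in either list, a selection made after the data were seen, it was −0.19, and that selection itself leaves out pairs that are moderate in both lists. Of 81 alternatives of the 9 chromosomes called in both lists, 71 kept the direction and the call, 9 kept the direction only, and the odds ratio of chromosome 1 in list 1 turned to 1.11 with a single peak per locus, where fewer peaks were tested. For the other moved values the cause was not tested.

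No paired analysis was possible because the lists hold no value per library, and for the same reason no library was left out in turn. The other settings fixed in advance, for transcript regions, cytosine-rich sequence, splice sites, target genes and gene lists, and with 1 peak per gene, were not run, since no annotation or sequence of hg19 was used here. The depth behind each fold is unknown.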

Other observations

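Enriched peaks were commoner where peaks lay close together. Among peaks with no other peak of their list within 10 kb on the strand, 0.539% were enriched in list 1 and 0.311% in list 2. With 1 to 4 such neighbours the shares were 1.85% and 1.22%, with 5 to 14 they were 3.71% and 2.84%, and with 15 or more they were 5.23% (95% exact interval 4.59 to 5.94) and 4.62% (4.06 to 5.24). No test was made of this trend, which was looked at after the lists had been seen. Peaks were counted unmerged here, and 49.7% and 61.3% of enriched peaks touched another peak of their list, against 10.8% and 11.9% of the others. How much of the rise came from the splitting of a site into several peaks was not tested.

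Some places were strongly depleted in both lists. A log2 fold of −3 or lower in both was found in 52 matched pairs, at 44 sites. The lowest lay on the plus strand of chromosome 14, at 50053524 to 50053570, with −9.46 in list 1 and −8.28 in list 2. It was followed by the plus strand of chromosome 1 at 28833872 to 28833917 (−4.82 and −5.32), the plus strand of chromosome 22 at 43011371 to 43011399 (−4.77 and −4.95) and the minus strand of chromosome 12 at 6690713 to 6690745 (−4.69 and −5.89). The −log10 p was 0 for each peak with a log2 fold of 0 or less, so the depletion rests on the authors' folds alone, with no p behind it.

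The test of the depleted sites and the 5000 nt window below were chosen after their results were seen, and all 3 patterns weighed below were found in the same lists on which they were tested. No biological explanation was tested, since the labels give no condition beyond immunoprecipitate and input, and tests of sequence and transcript regions need the annotation or sequence of hg19.

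On chromosome 19, the excess of enriched peaks may reflect wide peaks, crowded peaks or a few loci with many enriched peaks. Against peak width, the odds ratio within width quartiles was 2.15 in list 1 (95% interval 1.68 to 2.76) and 2.95 in list 2. Against crowding, it was 2.13 (1.76 to 2.58) and 2.16 (1.79 to 2.61) within classes of the number of peaks within 10 kb. Against a few loci, it was 3.15 (2.12 to 4.68) and 3.58 (2.61 to 4.89) with a single peak per locus. Base composition and transcript abundance were not tested and stay open, as no sequence of the build and no value per library was used here.

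Enriched sites lay near one another, which might come from the splitting of a site into several peaks. After peaks within 50 nt were merged, 22.5% of the enriched sites of list 1 and 21.1% of those of list 2 still had another on the strand within 1000 nt, against at most 5.64% and 4.90% in 1000 shuffles of which sites were enriched, so splitting over gaps of up to 50 nt does not account for it. Shuffling only among sites of the same width quartile and the same class of crowding reached at most 7.91% and 6.49%. Differences between those classes therefore do not account for all of it. Enriched sites had median widths of 112 and 126 nt, against 35 and 36 nt for other sites. Width was not matched within a quartile, so the shuffle cannot settle the part of wide sites. With a window of 5000 nt the shares were 31.6% and 29.6%, against at most 15.2% and 11.8%. Width and crowding within a class, splitting over wider gaps and several separate sites on a transcript stay open.

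The depleted places recurred between the lists. After merging, 71 of the 100 lowest sites of list 1 overlapped the 100 lowest of list 2. The 52 pairs at −3 or lower in both lists still made 44 separate sites once peaks within 50 nt were merged, so they were not a few places split into many peaks. Those pairs were chosen for being low in both lists, so this count cannot tell why the places recurred. An input library used for both lists may give such a recurrence, and whether there was such a library is not given in the sources used here. A strongly negative fold also needs many input reads, and whether high input alone brings these places together was not tested.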
